A study of Canis lupus familiaris with 9 samples.

How the data were processed

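RNA sequencing was done on 9 canine samples. Per the labels, 3 were CD4+ T cells sorted from healthy hounds, all female and 1 year old, and 6 were CD4+ peripheral T cell lymphomas (PTCL), a cancer of mature T cells. The labels place 3 lymphomas in Boxers: a male aged 6, a female aged 8 and a male aged 6 years. They place 3 in dogs of other breeds: females aged 3 and 4 and a male aged 11 years. The other breeds were Cavalier King Charles Spaniel, Rhodesian Ridgeback and Collie. Control and lymphoma samples therefore differ in breed, age and sex as well as in disease. The labels name sorting for the controls and do not give the tissue or any sorting of the lymphomas. Libraries are named here by group and replicate number. The labels of the 3 controls give the same details, and those of Boxer lymphomas 1 and 3 the same age and sex. Separate dogs are assumed there and not stated, and p-values measure the spread between these samples.

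Per the labels' protocols, messenger RNA was enriched with oligo(dT) beads, fragmented and copied with random hexamers. Whether the kit marked the strand is not given in the sources used here, so reads of a gene and an overlapping antisense gene may not be separable. Per the submitters' processing notes, TopHat2, HTSeq and DESeq2 were used with the dog genome build CanFam3.1. No versions are given there. The files hold no gene coordinates, so none are given.

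Each deposited file holds a signal per gene: the authors' read counts divided by 1 factor per library. Every value was a whole multiple of the value of 1 read (100% of values in each library, within a tolerance of 0.01 reads), so the whole reads could be recovered. The factors equalled median-of-ratios size factors recomputed over the 9 libraries (ratio 1 in each). The 28008 features comprise 24580 with Ensembl IDs and 3428 with IDs of gene models absent from Ensembl. A usable symbol accompanied 15305 features. For 22 features the symbol had become a number that looks like a date, and these were left without a symbol. The recovered reads numbered 11710623 to 18488468 per library. Genes of families with near-identical copies, such as the dog leukocyte antigen (DLA) genes, can share reads, and their values are uncertain in that respect.

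The design fixed before the data were examined named edgeR's quasi-likelihood test on raw counts. The deposited values are scaled counts, and limma on log2(value + 1) was used in its place, with empirical Bayes moderation and a mean-variance trend. The edgeR test that the design named was possible on the recovered reads. It was run as an alternative, added after seeing the data. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Genes with a value of at least 10 in at least 3 of the compared libraries were tested: 15977 for lymphoma versus control and 15112 for Boxer versus other-breed lymphomas. P-values were adjusted by Benjamini-Hochberg, and the threshold was an adjusted p of 0.05. Values are given as the mean normalised read count ± SD. Where a group had no reads, the fold is a lower bound from the reads pooled over each group, scaled by the group's summed size factors, with 3 reads in the group at 0, which covers counting error only.

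The comparisons were 6 lymphomas against 3 controls, and 3 Boxer lymphomas against 3 other-breed lymphomas without the controls. The genes named for the first comparison were fixed by rule: the 10 with the largest fold change in each direction among those with a symbol, past the threshold, with no overlap between the groups and a mean of at least 10 CPM, reads scaled to a common library total, in the higher group. To these were added 32 key genes of T cell and lymphoma biology whatever their result. Of these, 29 were found under their symbols, and CD4, BCL6 and CDKN2A were not analysed here. For the second comparison the rule took up to 8 genes per direction or, if fewer than 3 passed, the 3 with the smallest p. Up to 4 members per direction with the smallest p serve as examples of a gene list.

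In all, 34 gene lists were fixed before the data were examined. Most describe programmes of T cells and tumours, and 10 hold markers of other cell types. Each list with at least 3 measured members was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. An estimated correlation was the alternative. Members past the single-gene threshold were counted over all genes tested and adjusted over the list alone. A list score per library is the mean over members of the log2 value less the gene's mean over the 9 libraries. Shares of reads were compared with a two-sided exact permutation test over the 84 ways to choose 3 of 9 libraries, for which 0.0119 is the smallest p possible.

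The alternatives were other scaling factors, filters and pseudocounts (0.5 and 5), edgeR, DESeq2's Wald test, limma-voom with sample weights, a test against a fold change of 2, sex or age as a covariate, a replicate block, subsets of the dogs and leaving out each library. R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0 were used. The limma and camera steps were tested on simulated counts with 200 changed genes, drawn from the libraries' means and dispersions. For lymphoma versus control (16005 genes tested), 53.8% of genes changed by a fold of 4 and 10.4% of those changed by a fold of 2 were recovered. For Boxer versus other-breed lymphomas (15205 genes tested), the shares were 24.2% and 0%. Calls of unchanged genes numbered 6 of 72 and 1 of 25. The real lymphoma versus control comparison called 5596 genes, far more than the 200 changed here. A simulated gene had the same dispersion in every library, while the real median SD was 0.25 among controls and 0.56 among lymphomas. The shares recovered therefore do not give the power of the real comparison. A list raised by a fold of 2 in every member was recovered in both simulations, and 0 of the other lists were called. Genes were drawn independently there, so the simulations do not test calls of lists whose genes are correlated. For lymphoma versus control the estimated correlation of the mitosis list was 0.72. The chi-square of the reads per degree of freedom was at least 17.4 for every pair of libraries, so no library was counted as a repeat of another.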

Results

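Gene expression was measured in 9 libraries: 3 of sorted CD4+ T cells of healthy hounds, 3 of CD4+ PTCL of Boxers and 3 of CD4+ PTCL of dogs of other breeds. The labels of the 3 controls give the same details and do not state that they are separate dogs, so p-values measure the spread between samples. The libraries held 11710623 to 18488468 reads, and total reads did not pass a test between controls and lymphomas (exact permutation p = 0.75). On the first principal component, which held 51.3% of the variance, the 3 controls lay between -154 and -136 and the 6 lymphomas between 23.0 and 110. The second component (14.2%) set other-breed lymphomas 1 and 2 (-120 and -78.2) apart from the remaining libraries (11.3 to 58.8). The median SD of a gene on the log2 scale was 0.25 among the controls and 0.56 among the lymphomas.

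The first comparison asked which genes differ between CD4+ PTCL and normal CD4+ T cells. The lymphomas had higher cell division genes, GATA3 and CCND2, and lower genes of resting T cells, cytokine receptors, the interferon response and antigen presentation. Genes of macrophages, neutrophils, dendritic cells and stroma were higher as well. These list results passed camera at its preset correlation, and 0 of 34 lists passed with an estimated correlation (lowest adjusted p = 0.328). By limma, 3092 of 15977 genes were higher and 2504 were lower in lymphomas at an adjusted p under 0.05. The edgeR test on recovered reads gave 3092 and 2287. With age as a covariate the counts were 1048 and 885, and the controls were all younger than the lymphoma-bearing dogs. Without control 1, 2 or 3 the lower genes numbered 1328, 1194 and 1315, and without control 2 or 3 the higher genes numbered 1866 and 1999.

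Genes with the largest increases were almost silent in the controls. DAB1 (ENSCAFG00000018929), an adaptor of reelin signalling, had 5323 ± 4147 normalised reads in the lymphomas (n = 6) and 4.40 ± 6.84 in the controls (n = 3), a log2 fold change of 10.08 ± 1.18 (SE, limma adjusted p = 2.47e-04). SHROOM2 and HSPG2 (perlecan, a basement membrane proteoglycan) had no reads in any control and, from the reads pooled over each group, were at least 596-fold and 638-fold higher. HSPG2 was uneven, at 29.4 and 46.5 reads in other-breed lymphomas 1 and 2 and 487 to 1623 in the other 4, as was CLU, at 141 and 260 against 1906 to 5231. The peptide transporter SLC15A1 rose by 8.68 ± 1.27, the receptor phosphatase PTPRD by 8.78 ± 1.12 and the adhesion molecule NCAM1 by 8.52 ± 0.75. MEGF6 (8.90), CLU (8.20), CNNM1 (8.19) and the laminin gene LAMA2 (8.19) completed the 10 largest increases. The call of CLU ended with age as a covariate (log2 fold change 4.90, limma adjusted p = 0.0505). All controls were 1 year old, so the age slope came from the lymphomas alone. Among these, the dogs aged 3 and 4 had the lowest fibroblast and stroma scores (-1.55 and -1.93). The dog aged 11 had the highest (3.89). Fits with age therefore do not separate age from stromal content.

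The largest decreases included SULT2B1, a sterol sulfotransferase, at 0.569 ± 0.972 reads in lymphomas and 261 ± 133 in controls (log2 fold change -7.40 ± 0.68, limma adjusted p = 6.81e-05). IL21, a cytokine of helper T cells, fell by 7.11 ± 0.92 on the log2 scale, and PDCD1, which encodes the inhibitory receptor PD-1, by 5.88 ± 1.26. FST (-6.17), NPR3 (-5.98), KIAA1456 (-5.77) and ARNTL2 (-5.69) were in the same set, as were 3 T cell receptor V segments, TRAV29DV5 (-6.37), TRBV25-1 (-6.07) and TRBV15 (-5.64). FST ended with age as a covariate (-4.71, adjusted p = 0.147).

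Most genes of the cell division lists were higher. In the mitosis list, 32 of 32 measured members rose (32 adjusted over the list alone), with a median log2 fold change of 2.95 (camera adjusted p = 5.13e-20, adjusted p = 0.328 with an estimated correlation). TOP2A, the topoisomerase that untangles DNA before division, rose from 679 ± 31.7 to 12808 ± 4750 reads (log2 fold change 4.16 ± 0.28, limma adjusted p = 1.96e-05). ASPM, NUF2 and KIF20A rose by 2.97, 3.18 and 3.34, and the proliferation marker MKI67 by 2.68 ± 0.36. In the DNA replication list 25 of 31 rose and 0 fell (26 adjusted over the list alone), among them CDC6 (3.37), MCM5 (3.02), UHRF1 (2.98) and MCM2 (2.18). Its camera adjusted p was 1.03e-12, with an adjusted p = 0.328 with an estimated correlation.

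Of the G1 cyclins, CDKs and inhibitors, 7 of 17 rose and 2 fell (the same counts adjusted over the list alone). CCND2, a D-type cyclin, rose from 2373 ± 161 to 13446 ± 6404 reads (log2 fold change 2.38 ± 0.34), CDK4 by 1.69 ± 0.25, the transcription factor E2F3 by 3.12 and the inhibitor CDKN2C by 1.75. CDKN1B, which encodes the CDK inhibitor p27, fell from 16015 ± 1131 to 3186 ± 1480 reads (-2.48 ± 0.39, limma adjusted p = 0.00133, 0.0628 with age as a covariate), and RBL2 fell by 1.12. The camera adjusted p of the list was 0.0487, with an adjusted p = 0.44 with an estimated correlation. It was 0.0804 without Boxer lymphoma 1, 0.0837 without other-breed lymphoma 1, 0.0568 without control 2 and 0.0712 without control 3, and 0.0743 among female dogs alone. CCND1 (-1.29 ± 0.90), CCND3 (0.16 ± 0.15), CDK6 (0.43 ± 0.35), RB1 (0.41 ± 0.29) and CDKN2B (-0.48 ± 1.21) did not pass the threshold. With age as a covariate CCND1 (-4.02, adjusted p = 0.0178) and CDKN2B (-4.12, adjusted p = 0.0489) did. No lymphoma-bearing dog was as young as the controls, so the fit with age extrapolates beyond the lymphoma ages. The reads themselves differed little, at 52.9 ± 48.4 in lymphomas and 83.6 ± 20.7 in controls for CCND1. For CDKN2B, a low gene, they were 20.6 ± 20.5 and 16.5 ± 11.9.

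The transcription factors of T helper subsets moved in different directions. GATA3, the regulator of type 2 helper cells, rose from 2133 ± 188 to 8762 ± 2193 reads (log2 fold change 1.996 ± 0.23, limma adjusted p = 2.57e-04). TBX21, the regulator of type 1 helper cells, was at 104 ± 37.5 reads in controls and 33.4 ± 37.8 in lymphomas (-1.99 ± 0.64, limma adjusted p = 0.0356). That call ended in 7 of the 9 fits that each left out 1 library, where the adjusted p reached 0.135, edgeR gave 0.0996, and the age covariate gave 0.47. FOXP3, the regulator of regulatory T cells, fell by 2.52 ± 0.59. IL2RA, the alpha chain of the interleukin 2 receptor, fell by 3.03 ± 0.73, and its adjusted p was 0.0523 without control 1 and 0.0596 by edgeR. Other-breed lymphoma 3 had 1199 reads of IL2RA, above the 1130 and 1147 of controls 2 and 3. With the other-breed lymphomas only, limma gave an adjusted p of 0.0643 for FOXP3 and 0.0776 for IL2RA.

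As lists, the GATA3 and Th2 genes (2 of 16 rose, 3 fell), the TBX21 and Th1 genes (0 of 15 rose, 5 fell), the regulatory T cell genes (3 of 14 rose, 6 fell) and the checkpoint genes (2 of 12 rose, 4 fell) did not pass camera, with adjusted p of 0.133, 0.117, 0.444 and 0.468. Adjusted over the list alone, 6 Th1 genes fell and the other counts were as given. The chemokine receptor CCR4 rose with GATA3 (2.54), while JUNB (-3.16), IL4 (-2.88) and IL10 (-2.72) fell. IL2RB (-2.39) and IFNG (-3.56) were among the Th1 genes that fell. The Th1 list passed without control 3 (adjusted p = 0.0472) or other-breed lymphoma 3 (0.0329). LAYN (5.89), TNFRSF18 (2.21) and IKZF2 (1.44) rose in the regulatory list. CD96 (3.39) rose and LAG3 (-3.34), TIGIT (-3.98) and BTLA (-1.07) fell among the checkpoint genes.

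In the follicular helper list 1 of 13 rose, 5 fell and 7 did not pass (the same adjusted over the list alone), with a camera adjusted p = 0.0188 and an adjusted p = 0.328 with an estimated correlation. IL21, PDCD1, CXCR5 (-5.41) and SLAMF6 (-2.23) fell and TOX2 (2.04) rose. Without other-breed lymphoma 2 the camera adjusted p was 0.0699, and without other-breed lymphomas 1 and 2 it was 0.152. Genes of naive and resting T cells fell in 14 of 21 cases and rose in 0 (14 adjusted over the list alone), with a camera adjusted p = 1.88e-04 and an adjusted p = 0.328 with an estimated correlation. GIMAP8 fell by 3.52, the lymph node egress receptor S1PR1 by 3.89, the homing receptor CCR7 by 1.32 and FOXP1 by 1.51.

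Most genes of the T cell receptor complex did not pass the threshold. In the T cell receptor and signalling list 1 of 23 rose and 4 fell (the same adjusted over the list alone, camera adjusted p = 0.133). ZAP70 (-1.07), SIT1 (-1.05) and CD27 (-1.32) were among those that fell, and CD3G (0.50) rose. CD3E was at 16860 ± 3294 reads in lymphomas and 20699 ± 866 in controls (-0.32 ± 0.19, limma adjusted p = 0.211). CD5 was lower in every lymphoma, at 3255 ± 1496 reads against 10501 ± 201 (-2.09 ± 0.78), with an adjusted p of 0.0591 by limma and 0.0462 by edgeR, and 1.61e-04 without Boxer lymphoma 2, which had 265 reads. PTPRC (-0.29 ± 0.27), CD8A (1.02 ± 1.29) and SATB1 (0.52 ± 0.27) did not pass.

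In the chemokine receptor and adhesion list 4 of 28 rose and 10 fell (12 fell adjusted over the list alone), and camera did not pass (adjusted p = 0.0741). CCR9, a receptor of gut and thymus homing, rose from 309 ± 78.4 to 13295 ± 7306 reads (log2 fold change 5.29 ± 0.40). ITGAL (0.99) rose, while CCR6 (-3.77) and ITGA1 (-3.00) fell. The list passed without control 3 (adjusted p = 0.0394) or other-breed lymphoma 3 (0.0377).

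**Figure D1:**
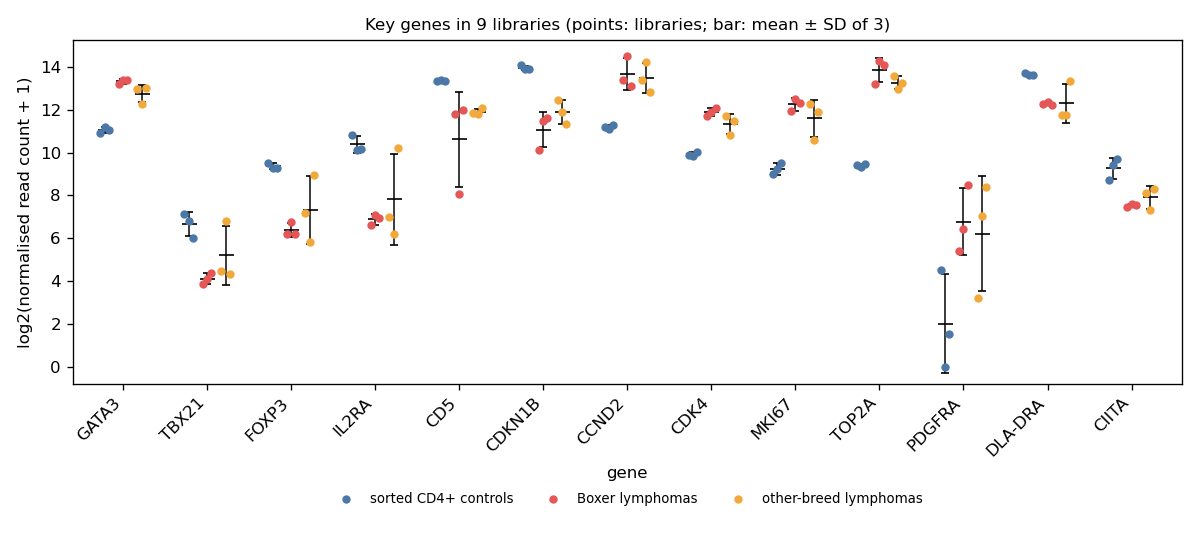
Normalised read counts of 13 key genes, on a log2(count + 1) axis, in each of the 9 libraries. Points are libraries coloured by group and bars are the mean ± SD of 3 libraries. GATA3, CCND2, CDK4, MKI67 and TOP2A lie higher in all 6 lymphomas than in all 3 controls, and CDKN1B, FOXP3, DLA-DRA and CIITA lie lower.

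Antigen presentation genes were lower in part. Of 13 measured MHC class II genes 9 fell and 1 rose (the same adjusted over the list alone, camera adjusted p = 0.00349, adjusted p = 0.412 with an estimated correlation). CIITA, the class II transactivator, fell from 640 ± 203 to 217 ± 65.6 reads (-1.55 ± 0.30), DLA-DRA by 1.37 ± 0.31, DLA-DQB1 by 1.88 and RFX5 by 1.12, while DLA-DOA rose by 1.55. Of 12 MHC class I genes 5 fell and 1 rose (7 and 1 adjusted over the list alone, camera adjusted p = 0.0207, adjusted p = 0.504 with an estimated correlation), and the list did not pass among female dogs alone (0.059). DLA-64 (-1.87), TAPBPL (-1.71) and TAP1 (-1.22) fell and the chaperone CALR (1.09) rose. In the interferon response list 17 of 29 fell and 0 rose (18 adjusted over the list alone, camera adjusted p = 4.91e-06, adjusted p = 0.412 with an estimated correlation). TRIM22 fell by 4.90, IRF9 by 1.40, OAS3 by 1.58 and IRF1 by 1.75. The interferon score varied within groups, from 0.53 to 1.65 in controls and from -1.66 to 0.44 in lymphomas.

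Cytokine signalling and immediate early genes were lower too. Of 25 JAK-STAT and cytokine receptor genes 11 fell and 0 rose (11 adjusted over the list alone, camera adjusted p = 9.24e-04, adjusted p = 0.328 with an estimated correlation), including STAT5B (-1.60), JAK3 (-0.95), TYK2 (-1.02) and IL2RB. Of 27 immediate early and stress genes 16 fell and 2 rose (17 and 2 adjusted over the list alone, camera adjusted p = 1.59e-04, adjusted p = 0.44 with an estimated correlation). FOSB (-5.63), JUNB (-3.16), JUND (-1.70) and KLF6 (-1.61) fell. The heat shock gene HSPH1 (1.98) and FOSL2 (2.10) rose. The controls were the only group named as sorted, and their scores were 1.20 in control 1, higher still in control 2 and 0.34 in control 3, against -1.39 to 0.08 in the lymphomas.

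Among genes of the PI3K, AKT and mTOR pathway, 8 of 29 fell and 2 rose (the same adjusted over the list alone, camera adjusted p = 0.113). PIK3R1, a regulatory subunit of PI3K, fell by 1.16 ± 0.22, with an adjusted p of 0.0697 with age as a covariate. PIK3R5 (-1.89) and FOXO1 (-1.50) fell and MTOR (0.51) rose. MYC, a transcription factor of cell growth, fell by 0.68 ± 0.16 on the log2 scale (limma adjusted p = 0.00817, 0.305 with age as a covariate). Of the BCL2 family and apoptosis genes 3 of 21 rose and 7 fell (the same adjusted over the list alone, camera adjusted p = 0.159). FAS (-3.75) and MCL1 (-1.24) fell and BID (1.40) rose. BCL2 itself was at 3649 ± 3101 reads in lymphomas and 2873 ± 1116 in controls and did not pass (adjusted p = 0.839). Its fitted change was -0.26 by limma and 0.35 by edgeR.

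Biosynthetic lists rose in part. Of the MYC targets and ribosome biogenesis genes 12 of 30 rose and 1 fell, which was MYC itself (15 and 1 adjusted over the list alone, camera adjusted p = 0.0117, adjusted p = 0.491 with an estimated correlation). NOLC1 (0.86), PA2G4 (0.91) and WDR12 (0.77) rose. Of the oxidative phosphorylation genes 11 of 22 rose and 0 fell (12 adjusted over the list alone, camera adjusted p = 0.00635, adjusted p = 0.371 with an estimated correlation), among them UQCRC2 (1.31), NDUFV1 (1.61) and SDHB (0.79). Reads of the 13 mitochondrial genes took 9.67 ± 3.26% of the reads in lymphomas and 3.12 ± 0.32% in controls, and ribosomal protein genes 3.13 ± 0.67% and 5.79 ± 0.24% (both exact permutation p = 0.0119, adjusted p = 0.0298 over 5 measures). Of the glycolysis genes 5 of 21 rose and 1 fell (the same adjusted over the list alone, camera adjusted p = 0.159), with PFKP (2.64), GAPDH (1.95), TPI1 (1.23) and HK2 (2.20) higher and SLC2A3 (-1.99) lower. Of the chromatin and signalling genes recurrently mutated in human PTCL, 5 of 25 rose and 5 fell (the same adjusted over the list alone, camera adjusted p = 0.756). The methyltransferase gene EZH2 (2.07), RHOA (0.67) and IDH2 (1.13) rose, and the demethylase gene KDM6A (-1.57), PLCG1 (-1.17) and KMT2D (-0.76) fell.

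Of the 10 lists of other cell types, 5 passed camera upwards. Of 16 monocyte and macrophage genes 14 rose and 0 fell (16 adjusted over the list alone, camera adjusted p = 1.84e-06, adjusted p = 0.412 with an estimated correlation). APOE rose from 13 to 2214 reads (log2 fold change 6.68 ± 0.97), the lysozyme gene LYZ by 5.34, TYROBP by 5.26 and C1QC by 3.62. Of 8 neutrophil genes 7 rose (7 adjusted over the list alone, camera adjusted p = 0.00296, adjusted p = 0.328 with an estimated correlation), including S100A12 (4.27) and MPO (3.63). Of 13 dendritic cell genes 7 rose (9 adjusted over the list alone, camera adjusted p = 0.00216, adjusted p = 0.412 with an estimated correlation), including CLEC9A (4.54) and XCR1 (4.42). Of 17 fibroblast and stroma genes 9 rose (11 adjusted over the list alone, camera adjusted p = 0.00216, adjusted p = 0.504 with an estimated correlation), including MMP2 (6.77) and COL6A1 (6.45). Of 14 endothelial genes 6 rose (7 adjusted over the list alone, camera adjusted p = 0.0117, adjusted p = 0.504 with an estimated correlation), including ESAM (4.62) and CDH5 (5.65). In these lists 0 genes fell.

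The stromal markers were uneven among the lymphomas. The fibroblast and stroma score was -1.55 and -1.93 in other-breed lymphomas 1 and 2, 1.87 to 3.89 in the remaining 4 lymphomas and -3.11 to -2.49 in the controls. The macrophage score was -0.73 to 2.66 in the lymphomas and -2.89 to -2.47 in the controls. Among female dogs alone, which include both low-scoring lymphomas, the stroma, endothelial, dendritic cell and receptor tyrosine kinase lists did not pass (camera adjusted p = 0.151, 0.609, 0.151 and 0.103). Without other-breed lymphomas 1 and 2, a choice made after seeing the data, limma called 3550 genes higher and 2696 lower, of which 2755 and 2286 were shared with the full comparison.

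Receptor tyrosine kinases and their ligands followed a similar course. Of 24 measured genes 12 rose and 1 fell (the same adjusted over the list alone, camera adjusted p = 0.00351, adjusted p = 0.464 with an estimated correlation). IGF1 rose by 6.18, PDGFA by 4.27 and FLT3, also in the dendritic cell list, by 2.45. CSF1R, also in the macrophage list, rose by 5.44, while IGF1R fell by 2.08. PDGFRA rose by 4.49 ± 1.26 (limma adjusted p = 0.0197), with an adjusted p of 0.103 without control 2 and 0.0753 without control 3. With age as a covariate it was 2.16 (0.455), and with sex 3.56 (0.0876). PDGFRB rose by 5.34 ± 1.84 (adjusted p = 0.0451), which ended in 7 of the 9 fits that each left out 1 library, where the adjusted p reached 0.135. The age covariate gave PDGFRB -0.10. The dogs of other-breed lymphomas 1 and 2, the youngest with lymphoma, had the lowest stroma scores, and the oldest had the highest. These age fits therefore do not separate age from stroma. The score of the receptor list was -0.99 and -0.44 in other-breed lymphomas 1 and 2 and 0.86 to 2.21 in the other lymphomas. KIT was at 389 ± 602 reads in lymphomas and 24.7 ± 21.1 in controls (2.74 ± 1.40, adjusted p = 0.149, and 0.0222 without other-breed lymphoma 1).

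A further 5 lists of other cell types did not pass camera. B cell genes (0 of 15 rose, 1 fell), plasma cell genes (1 of 9 rose, 2 fell), cytotoxic T and NK cell genes (2 of 12 rose, 1 fell), platelet genes (2 of 4 rose) and erythroid genes (1 of 3 rose, 1 fell) had camera adjusted p of 0.133, 0.735, 0.996, 0.325 and 0.907, with the same counts adjusted over the list alone. The B cell list passed, downwards, without Boxer lymphoma 2 (adjusted p = 0.0455). PRF1, which encodes perforin, rose by 2.54, and NCR3 fell by 2.56. None of the 34 lists passed with an estimated correlation, the lowest adjusted p being 0.328. The members and counts of 1 of the 34, which did not pass camera, are not given here.

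**Figure D2:**
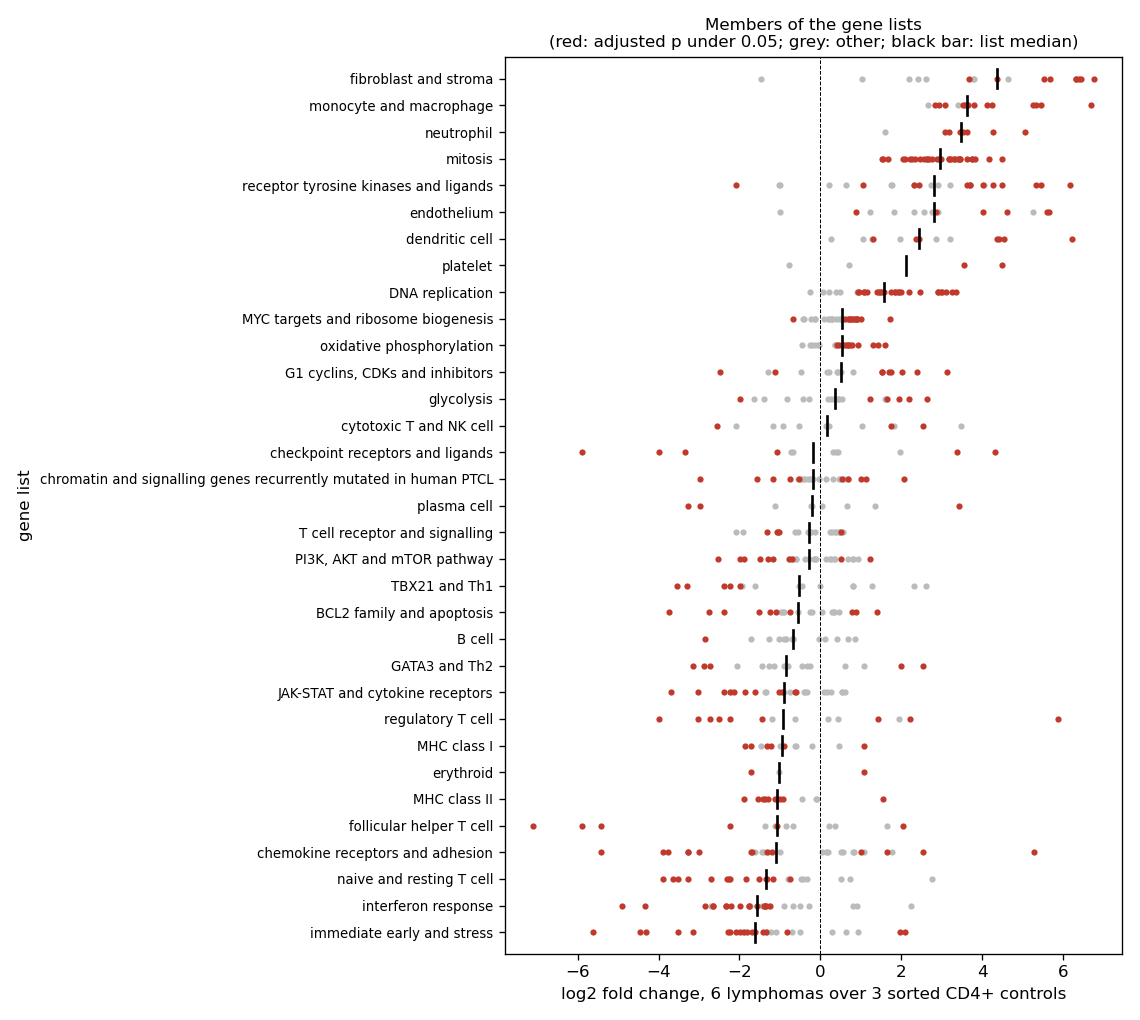
Log2 fold change of each measured member of 33 gene lists, 6 lymphomas over 3 controls. Each point is a gene, red where its limma adjusted p is under 0.05 and grey otherwise, and the black bar is the list median. The medians run from -1.61 for immediate early genes to 4.37 for fibroblast and stroma genes, and all 32 mitosis genes lie above 0.

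T cell receptor V segments were singled out after their values were seen, because 3 were among the largest decreases. Of 11 segments with a symbol 10 were tested and 7 were lower in lymphomas by limma. Each control had reads of every segment, while 53 of the 66 pairs of a segment and a lymphoma lay under 10% of the control mean. Of the other 13 pairs, 4 lay above the control mean. TRBV16 had 23157 reads in Boxer lymphoma 2 and 11196 in other-breed lymphoma 1, against 1864 ± 487 in controls. TRAV34 had 1380 reads in Boxer lymphoma 2, against 117 ± 16.7, and TRAV24 had 342 in other-breed lymphoma 3, against 128 ± 30.0. The constant segment TRAC did not pass the threshold (log2 fold change -0.13 ± 0.38).

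**Figure D3:**
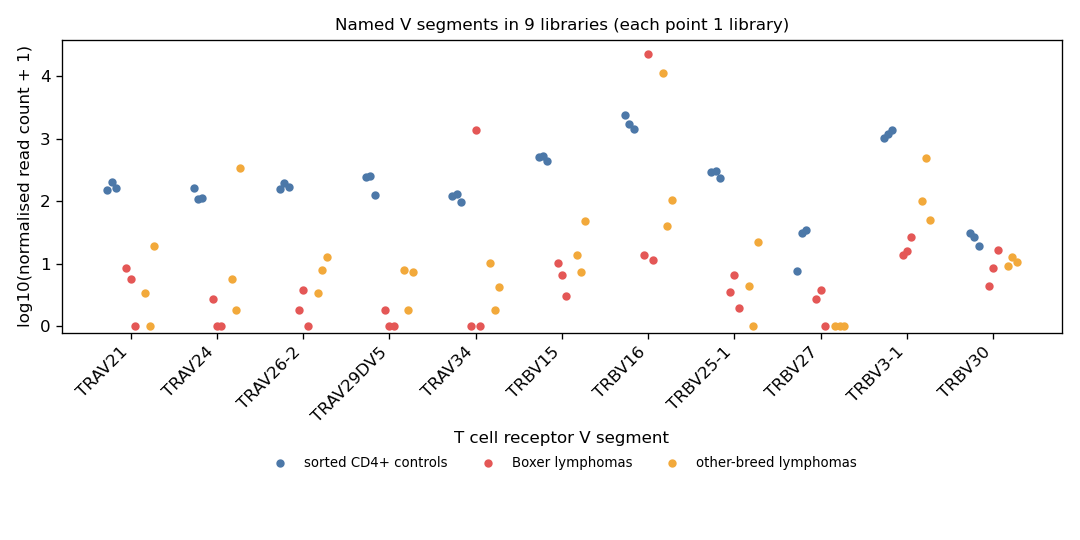
Normalised read counts of 11 named T cell receptor V segments, on a log10(count + 1) axis, in each of the 9 libraries, coloured by group. The 3 controls lie close together in most segments, and the lymphomas lie lower except for single libraries, such as TRBV16 at 23157 reads in a Boxer lymphoma.

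The second comparison asked whether lymphomas of Boxers differ from those of other breeds. Boxer lymphomas 1 and 3 and other-breed lymphoma 3 came from males and the rest from females. Ages were 6 to 8 years in Boxers and 3 to 11 in the other breeds. With sex or with age as a covariate limma called 0 genes. The list tests were run without these covariates, so list differences between breeds are not separated from sex and age. By limma 0 of 15112 genes were higher and 0 were lower at an adjusted p under 0.05, with 753 at an unadjusted p under 0.05 and a smallest adjusted p of 0.182. The edgeR test on recovered reads also called 0 genes (732 at an unadjusted p under 0.05), and DESeq2 called 49 higher and 69 lower. The genes with the smallest p were ESYT1, NFIL3 and MYB. ESYT1, a tether between membranes, was at 2650 ± 668 reads in Boxer and 949 ± 99.1 in other-breed lymphomas (log2 fold change 1.46 ± 0.23, limma adjusted p = 0.472). The transcription factor NFIL3 was at 38.6 ± 17.5 and 392.1 ± 146 reads (-3.35 ± 0.54, limma adjusted p = 0.496). MYB, a transcription factor of blood progenitors, was at 6226 ± 1315 and 1864 ± 577 reads (1.77 ± 0.29, limma adjusted p = 0.51), with 420 ± 200 in the controls. DESeq2 gave these 3 genes adjusted p of 0.00259, 2.00e-06 and 0.00261.

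Of 33 lists tested between the breed groups 12 passed camera at the preset correlation, 8 higher and 4 lower in Boxers. By limma 0 of their members passed over all genes. Adjusted over the list alone, 1 immediate early and stress gene rose and 0 members of the other 11 passed. All 12 had an adjusted p = 0.726 with an estimated correlation. Higher in Boxers were the lists of mitosis (median log2 difference 0.66, camera adjusted p = 5.29e-10), DNA replication (0.29, 4.22e-04), fibroblast and stroma (2.71, 2.12e-04), monocyte and macrophage (1.40, 2.85e-04), immediate early and stress (0.71, 2.85e-04), endothelium (1.92, 0.00251), B cell (0.98, 0.00612) and receptor tyrosine kinase genes (1.25, 0.00612). Lower in Boxers were the lists of neutrophil (-1.84, 0.0025), Th1 (-0.92, 0.00612), cytotoxic T and NK cell (-0.86, 0.01) and MHC class I genes (-0.34, 0.0429). Other-breed lymphoma 3 had the highest score of the 6 lymphomas for the stroma (3.89), endothelial (3.28), receptor (2.21) and immediate early (0.08) lists, and other-breed lymphomas 1 and 2 the lowest (-1.55 and -1.93 for stroma, -1.78 and -1.70 for endothelium). TPX2 was at 3805 ± 239 reads in Boxer and 1939 ± 823 in other-breed lymphomas, C1QC at 189 ± 21 and 67 ± 32, and S100A12 at 17 ± 11 and 69 ± 14. The cytotoxic ligand FASLG was at 9 ± 6 and 140 ± 131 reads. The stroma, DNA replication, immediate early, endothelial, B cell and receptor lists did not pass without other-breed lymphoma 2 (camera adjusted p = 0.137, 0.135, 0.0862, 0.227, 0.488 and 0.088). Without other-breed lymphoma 1 the receptor, macrophage, endothelial and MHC class I lists did not pass (0.323, 0.0706, 0.0693 and 0.178), nor did the Th1 and MHC class I lists without other-breed lymphoma 3 (0.0501 and 0.301). Without Boxer lymphoma 1 the Th1, cytotoxic and MHC class I lists did not pass (0.0791, 0.0791 and 0.667), without Boxer lymphoma 2 the B cell list (0.0961), and without Boxer lymphoma 3 the receptor, cytotoxic, endothelial and MHC class I lists (0.11, 0.0932, 0.0677 and 0.164). The mitosis and neutrophil lists passed whichever lymphoma was left out. A further 21 lists had camera adjusted p between 0.309 and 0.858.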

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

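The splits of the libraries, and the rule that left the macrophage test below undecided, were chosen after the results were seen, while the stroma and macrophage tests themselves were planned.

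Single libraries stood apart from the other 5 lymphomas by Dixon's test in 9 of the 88 groups of 6 values tested. Chance flags about 1 in 20 groups, or 4.4 of 88. Boxer lymphoma 1 had 126 reads of SLC15A1 against 3500.1 to 10964 in the others, and Boxer lymphoma 2 had 265 reads of CD5 against 3546 to 4320. Other-breed lymphoma 2 had 110.4 reads of TBX21 against 13.6 to 21.2, and 1557 of MKI67 against 3811 to 5856. Other-breed lymphoma 3 stood apart in 5 values: 1199 reads of IL2RA against 73.3 to 135, a regulatory T cell score of 0.83 against -0.59 to -0.07, a JAK-STAT score of 0.38 against -0.75 to -0.37, 15.9% mitochondrial reads against 6.76 to 9.78%, and 16.2% of reads in its 10 most abundant features against 7.50 to 10.6%. IL2RA is a member of both of these lists, and both read shares can count the same reads, so the 5 values are not independent. No explanation of these single values was tested.

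Between Boxer and other-breed lymphomas 12 gene lists differed by camera at the preset correlation, and 0 did with an estimated correlation. The adjusted p were 5.29e-10 for mitosis, 4.22e-04 for DNA replication, 2.12e-04 for fibroblast and stroma, 2.85e-04 for macrophage and for immediate early genes, and 0.00251 for endothelium. They were 0.0025 for neutrophil, 0.00612 for Th1, for B cell and for receptor tyrosine kinase genes, 0.010004 for cytotoxic and 0.0429 for MHC class I genes.

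The number of genes past the threshold was compared with other splits of the same libraries. For lymphoma versus control, 1 of 84 splits gave as many as the real 5596, the real split itself, and the highest other gave 2. That share is the smallest possible with 84 splits. A random split of these libraries is thus unlikely to give such a count, if the controls are separate dogs. The 10 splits of the 6 lymphomas are too few for a share under 0.05, with 0 genes in the real split and 1 in the highest other. Among female dogs only, 2196 genes were higher and 2139 lower, of which 2004 and 1887 were shared with the full comparison, so sex is not the whole cause. Breed and age differ along with disease and remain open, as does sorting, which is not stated for the lymphomas.

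Genes higher in lymphomas may reflect other cells in the lymphoma samples, since markers of stroma and macrophages were higher. With the fibroblast and stroma score as a covariate, 1195 of the 3092 higher genes (38.6%) stayed past the threshold, between the bounds of 20% and 50% written beforehand. The median log2 fold of the 3092 went from 1.76 to 1.42 and its median SE from 0.34 to 0.48. The median of the stroma list went from 4.37 to 0.25, which follows from the score being the mean of its members. With the endothelium score, a covariate without a bound of its own, 1557 genes (50.4%) stayed and the median log2 fold was 1.496. With the macrophage score 189 genes (6.11%) stayed, which is under the 20% written beforehand as the mark of a cause. That bound was set aside after the fits were seen, because the score correlates with disease at 0.89 and the median SE rose by a factor of 2.18, from 0.34 to 0.74. The median fold went from 1.76 to 1.26, and 90.8% of the genes kept a positive change. Calls thus ended through a wider error more than a smaller fold, and the share from macrophages cannot be told apart from disease. No biological explanation was tested against these.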

How the results depend on the processing

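The pseudocounts, TMM-scaled values, edgeR with TMM and the fits without other-breed lymphomas 1 and 2 were added as alternatives after seeing the data. Of these, edgeR with TMM was the test that the design had named. For lymphoma versus control, the genes higher and lower (3092 and 2504) were 711 and 341 against a fold change of 2 and 1048 and 885 with the age covariate. They were 4428 and 3983 in limma-voom with sample weights and 4165 and 2641 in the DESeq2 Wald test. Leaving out each library gave 1866 to 3291 higher and 1194 to 2605 lower. The replicate block gave 2752 and 2158, and 0 genes between breeds, but replicates of the same number share only a name (correlations -0.14 to 0.10). For Boxer versus other-breed lymphoma (0 and 0), the DESeq2 Wald test gave 49 higher and 69 lower, pseudocount 5 gave 2 lower, all 9 libraries in 3 groups gave 2 higher, and leaving out each library gave 0 to 1 in each direction.

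Reversals were limited to genes and lists not past the threshold, apart from PDGFRB. CDKN2B (-0.48) was 0.33 with DESeq2 size factors in edgeR, 0.27 with upper-quartile factors, 0.33 in the DESeq2 Wald test, 0.17 in limma-voom, 0.31 in edgeR with TMM, 0.54 in Boxer lymphomas only, 0.80 without other-breed lymphomas 1 and 2, and -0.90 to 0.21 leaving out each library. BCL2 (-0.26) was 0.34, 0.31, 0.35 and 0.35 with DESeq2 factors, upper-quartile factors, the DESeq2 Wald test and edgeR with TMM, 0.28 with the age covariate, 0.11 in other-breed lymphomas only and -0.64 to 0.32 leaving out each library. PTPRC was 0.041 with the sex covariate and in female dogs only, and 0.18 with the age covariate, which also gave KIT -0.17 and PDGFRB -0.10. CD8A was -0.60 in Boxer lymphomas only and -0.077 without other-breed lymphomas 1 and 2. The cytotoxic list turned with adjusted p of 0.697 to 0.936 over the fits leaving out each library (6 of 9) and 0.699 without other-breed lymphomas 1 and 2, and the chromatin list with 0.923 in female dogs only. The median log2 fold of all genes was 0.05 by limma and 0.12 by edgeR with TMM.

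Over all alternatives of lymphoma versus control, named genes kept direction and side of the threshold in 1253 cases, lost the call in 62 and gained one in 21, with 24 reversals. Lists did so in 431, 31, 5 and 8. Between breeds the 3 named genes kept theirs in 60 cases and gained a call in 3, by DESeq2, and the 12 lists kept theirs in 76 and lost it in 32. The 21 lists not past the threshold between breeds were followed only as the range in the report.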

Other observations

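The V segment tests were chosen after their values were seen, as was the interval used for the CCR9 test, while the list of precursor genes and its bounds were written beforehand.

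T cell receptor V segments were lower in lymphomas by a median log2 fold of -5.13 over the 10 tested. Fewer T cells in the samples would lower the constant segment and CD3E alike. TRAC changed by -0.13 ± 0.38 and CD3E by -0.32 ± 0.19, so that even 2 SE below they lie at -0.90 and -0.69, far above the V segments. A candidate explanation is that one clone dominates each lymphoma and carries few V segments, which these values leave open. In 3 of 6 lymphomas (Boxer 2, other-breed 1 and other-breed 3) a named segment reached the lowest control value with no second of its chain. In the other 3 (Boxer 1, Boxer 3 and other-breed 2) none of the 11 named segments did, so this cut shows no clone there. It cannot exclude one, since in other-breed 2 TRBV3-1 had 489 reads, under the 1036 to 1399 of the controls, yet led its named beta segments. The most abundant segment took 99.8%, 98.9% and 89.5% of the reads of named beta segments in Boxer 2, other-breed 1 and other-breed 2. It took 30%, 47.2% and 45.2% in Boxer 1, Boxer 3 and other-breed 3, against 40.7 to 56.0% in controls. Those lymphoma shares rest on few reads, with 12.7, 26.0 and 105 normalised reads of the top segment, against 1465 to 2406 in controls. TRAC was at 17231, 7209 and 7916 reads in the same lymphomas. Their shares therefore do not show a mixture of segments like that of the controls. Segments without a symbol and junction sequences were not analysed here.

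CCR9, found at 13295 ± 7306 reads in lymphomas (6112 to 26420) and 309 ± 78.4 in controls (222 to 375), is also a gene of developing T cells in the thymus. A thymocyte-like programme may accompany it. Of 13 measured precursor T cell genes 3 rose: LMO2 (1.65 ± 0.58), CD1E (4.38 ± 1.13), which dendritic cells also express, and AEBP1 (2.71 ± 0.64). AEBP1 moved with the stromal markers, at 81.2 and 89.1 reads in other-breed lymphomas 1 and 2 and 157 to 456 in the remaining lymphomas. The share that rose was 23.1%, under the 25% written beforehand as counting against the programme. The list did not pass camera (p = 0.153, 0.487 with an estimated correlation), which was also written as counting against it. By the bounds written beforehand, the outcome thus counts against the programme. The exact 95% interval of the share, 5.04 to 53.8%, spans values on the other side of both bounds. It treats the genes as independent draws and leaves out the genes too low to test. It therefore does not overturn that outcome, though 13 genes leave the share uncertain. A further 7 genes were too low to test: RAG1 and LYL1 are listed at 0 in all 9 libraries, and RAG2 and PTCRA reached at most 3.4 and 2.5 reads. DNTT had 2277 reads in Boxer lymphoma 2 and 1.7 to 179 in the other lymphomas.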
